A study of Homo sapiens with 24 samples.

How the data were processed

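The series compared commercial polyA RNA of human fetal heart and adult heart on 24 Agilent microarrays with 2 colours. Each array carried one RNA labelled with the red dye Cy5 and one labelled with the green dye Cy3. Fetal RNA was red and adult RNA green on 11 arrays, and the dyes were swapped on 7 arrays. A further 3 arrays carried adult RNA in both colours and 3 carried fetal RNA in both colours. The 18 arrays that set fetal against adult RNA are called mixed arrays here, and the other 6 self arrays. The arrays lay on 3 slides of 8. Each slide held every kind of array.

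Per the labels, the RNA was amplified and labelled by the array maker's usual protocols, the images were read with Feature Extraction version 7.5, and features that were saturated or outliers were removed before deposit. The deposited values are log ratios per spot, and were taken as log10 of red over green, which is how Feature Extraction writes its ratio. The table itself states neither the base, nor the centring, nor the direction of the ratio. Direction is therefore called likely, from the dyes in the labels and the software's convention. Values ran from -2 to 1.42, with 886 values at the lower end of the range, none of them on a spot with a gene name. An exact 0 stood in 693 values, 57 of them on spots with a gene name. The median of each array over all spots was -0.21, -0.22, -0.21, -0.20 and -0.21 on the log10 scale for the fetal red arrays of slide 1, -0.19, -0.21 and -0.20 on slide 2, and -0.19, -0.20 and -0.21 on slide 3. It was 0.05 for the adult red array of slide 1, 0.05, 0.05 and 0.05 on slide 2, and 0.04, 0.04 and 0.03 on slide 3. It was 0, -0.000685 and -0.000717 on the adult self arrays and -0.00521, -0.00266 and -0.00723 on the fetal self arrays.

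The table held 1886 spots, of which 1664 to 1854 had a value on a given array. Between 32 and 222 spots were missing per array, most often on slide 3 (158 per array on average, against 95.5 on slide 1 and 57.8 on slide 2). The platform's gene table named 1155 spots, and 1143 of these matched a gene of the current human reference annotation (GRCh38.p14, used for names alone) by its gene number. A further 731 spots had no name there. Of the named spots, 2 were left out by a rule that drops XIST, TSIX and genes of the Y chromosome, 1151 carried 1 gene symbol and 2 carried several. Other genes of the X chromosome were kept. The analysis used these 1153 named spots, called probes, because the table gives no marks for control spots, and 155 unnamed spots had a mean log2 ratio below -1 on the self arrays, as no named probe did. Spots without a name are described in the closing section.

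The log10 ratios were converted to log2 with no further centring. A linear model was fitted to each probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). Its terms were an intercept, which is the probe's dye bias, and the polarity of the array, coded 1 for fetal in red, -1 for adult in red and 0 for a self array. The polarity coefficient is the log2 ratio of fetal over adult RNA. A probe needed at least 3 values in each dye orientation, which 1119 probes met and 34 did not. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 with an absolute log2 fold of at least 1. A dye bias was called at an adjusted p under 0.05 with an absolute log2 of at least 0.5. Adult and fetal self arrays were compared with limma at an adjusted p under 0.05, with at least 2 values per group.

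As far as the labels say, every array held the same pair of RNA preparations. The arrays are then technical replicates, there is 1 RNA of each stage, and no p-value measures the spread between hearts. Each is set against the spread between arrays alone. In the fetal over adult fit all arrays shared 1 dye term, so this spread also held the difference in dye bias between adult and fetal self arrays. PGAM2 had SDs of 0.0155 and 0.0178 within the fetal red and adult red arrays. Its SE was 0.0365, with self means of 0.498 for adult and -0.0997 for fetal RNA. No signal intensities were used here, so only the number of arrays and the rounding of the values can be given as limits on precision. Most deposited ratios stood in steps of 0.0332 on the log2 scale. Some SEs, such as 0.00597 for RPL21, lay under that step, so spread smaller than the step is partly hidden.

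Gene lists were fixed before the data were examined: 15 lists of pathways and gene families, and 12 lists of markers of cell types or tissues that the RNA could hold. The latter covered endothelial cells, smooth muscle cells and pericytes, fibroblasts, adipocytes, macrophages and monocytes, lymphocytes, neutrophils and mast cells, neurons and Schwann cells, epicardium and mesothelium, liver, skeletal muscle and lung. Lists with at least 5 measured genes were tested against all other genes with limma's cameraPR on the moderated statistic (two-sided, preset correlation 0.01, 1 probe per gene), with Benjamini-Hochberg adjustment over the 7 lists tested. The probe with most values stood for a gene with several probes, with ties broken by the smaller residual spread. Of 60 genes with several probes, 11 had probes on both sides of the threshold, and 7 had probes of opposite sign. The genes named in the text followed a rule, also fixed before the data were examined. It took the 10 probes with the largest fold each way among those called with the same sign on every mixed array, up to 3 called members of each list (or up to 2 measured members where none was called), a set of 17 textbook fetal or adult genes wherever measured, and the 3 probes with the largest dye bias.

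The fits were tested on simulated arrays with the real missing values and independent normal noise, whose SD per probe came from the data. For the comparison of fetal with adult RNA over 1119 probes, all probes given a log2 change of 1.5 or 2 were called (100% each), none given 0.7 passed the fold minimum (0%), and 0 of 919 unchanged probes were called. With so small a spread between arrays the fold minimum decided these outcomes. Without it, 10 of the 919 unchanged probes were called. For the comparison of the self arrays over 1071 probes, 15.4% of changes of 0.2 and 67.7% of changes of 0.5 were called, with 7 calls among 887 unchanged probes. The SD used there was taken over adult and fetal self arrays together. It therefore counts the real difference between these groups as noise, and the shares do not give the power of the real comparison.

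Alternatives covered centring and scaling of the arrays, the self arrays, the dye term, the slide as a fixed or random block, 1 value per slide, each orientation and each slide alone, filters on missing values, array weights, other fold minimums, leaving out each slide or array, and values read as log2 already. The use of unnamed spots, the treatment of exact zeros as missing and a narrower signalling list were added after seeing the data. Their effect is given in the closing section, with no separate value for the narrower list.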

Results

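The series profiled RNA of human fetal and adult heart on 24 arrays, and its title names heart tissue expression as the subject. The 18 mixed arrays measured the ratio of fetal over adult RNA for 1119 probes of 1053 genes. The 6 self arrays gave the background, since both channels held the same RNA. All signs below are fetal over adult, a direction that is likely rather than stated, from the dyes in the labels. Errors are standard errors of the fitted log2 fold over the mixed and self arrays of 1 RNA pair. They include the dye bias that differed between adult and fetal self arrays. The number of mixed arrays behind a value is 18 unless another number is given.

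The largest difference towards fetal RNA was that of SPP1, the secreted matrix protein osteopontin, at a log2 fold of 4.41 (SE 0.0292), or 21.3-fold. CDH16, a cadherin best known from kidney epithelium, followed at 3.88 (SE 0.0375). KIF20A, a kinesin of cell division, stood at 2.13 (SE 0.0829), IGF2BP1, an RNA-binding protein of fetal tissues, at 2.10 (SE 0.0573), and COL5A2, a fibrillar collagen chain, at 1.97 (SE 0.0124). The next 5 probes lay between 1.25 and 1.34. These were MAFF, a small transcription factor (1.34, SE 0.016, 13 arrays), RSPH1, a radial spoke protein of motile cilia (1.33, SE 0.0646), JPT1 (1.33, SE 0.0234, 15 arrays), ORC6, a subunit of the origin recognition complex (1.29, SE 0.0482), and CCNA2, the cyclin A of dividing cells (1.25, SE 0.0621). Each was higher in fetal RNA on every mixed array with a value.

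The largest difference towards adult RNA was that of DYNC1I1, an intermediate chain of cytoplasmic dynein, at -4.12 (SE 0.0501), or 17.4-fold. CHGB, a protein of secretory granules, stood at -3.39 (SE 0.0367), with its other probe at -2.32, and FAM81B at -3.22 (SE 0.0945). THRSP, a regulator of fat synthesis, was at -3.16 (SE 0.0593), and ADIPOQ, the fat cell hormone adiponectin, at -3.06 (SE 0.0273). SFTPC, the lung surfactant protein C, was at -3.03 (SE 0.0336), VIT, a matrix protein, at -2.96 (SE 0.0678), and F5, a coagulation factor, at -2.88 (SE 0.0434). HOMER2, a scaffold protein, was at -2.84 (SE 0.0422), and ISCU, the scaffold for iron-sulphur clusters, at -2.72 (SE 0.0163, 17 arrays). Each was higher in adult RNA on every mixed array with a value. Adjusted p-values from limma for these 20 probes ran from 8.51e-36 (COL5A2) to 3.01e-16 (CCNA2).

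**Figure D1:**
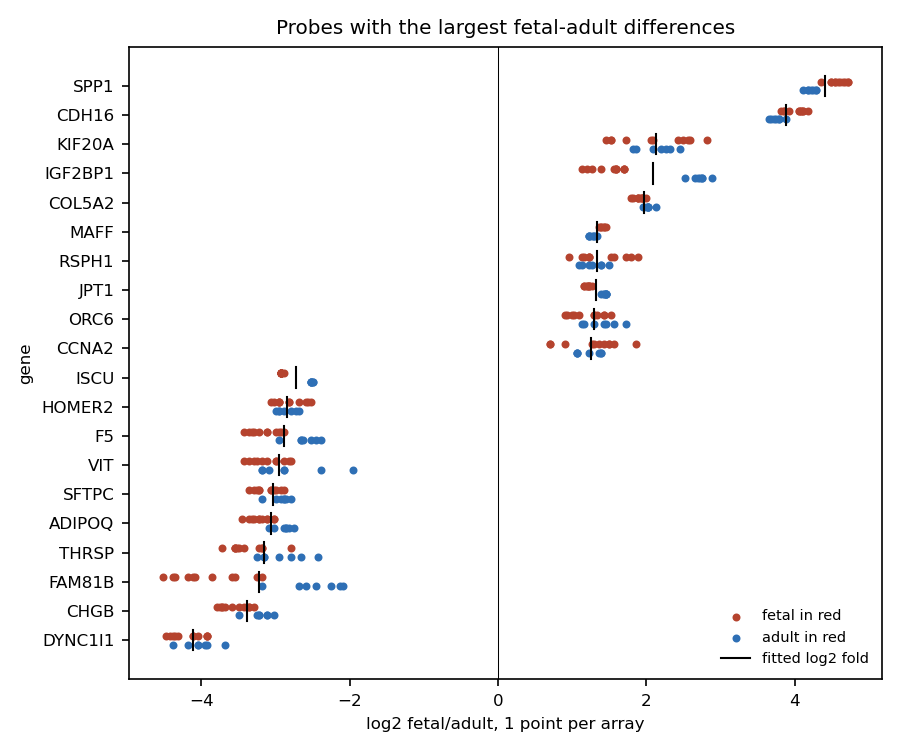
Log2 ratio of fetal over adult RNA (horizontal axis) for the 10 probes with the largest fold each way (vertical axis), 1 point per mixed array, coloured by dye orientation, with a bar at the fitted log2 fold. The points of SPP1 surround 4.41 and those of DYNC1I1 surround -4.12, while IGF2BP1 and FAM81B separate by orientation.

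Of the 1119 probes, 384 were called by limma, 16 higher in fetal RNA and 368 higher in adult RNA (4.17% and 95.8% of the calls). With the ratio turned the other way, the 368 would be higher in fetal RNA and the 16 in adult RNA. If the values were log2 rather than log10, 4 probes would be called, 2 each way. All 384 had the same sign on every mixed array with a value. The calls fell on 16 genes higher in fetal RNA and 332 higher in adult RNA, of 1053 genes. Counts of list members below are to be read beside these shares. Folds formed 2 clusters, with 474 probes within 0.25 of 0 and 602 probes below -0.5 (median -1.10), and with 7 probes between -0.5 and -0.25. Within slide 1, 2 and 3 alone, 418, 367 and 377 probes were called, and 379 with the slide as a block. Subtracting each array's median moved the median fold of all probes up by 0.66 and gave 125 calls, 112 of them among the 384, with 29 higher in fetal RNA and 96 higher in adult RNA (76.8%). The median fold was -0.74 over all probes, inside the lower cluster, but -0.19 over the 867 probes with a value on every array. Subtraction therefore moves probes near 0 to the fetal side. The right zero stays open, so folds below are to be read beside the counts with medians subtracted.

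**Figure D2:**
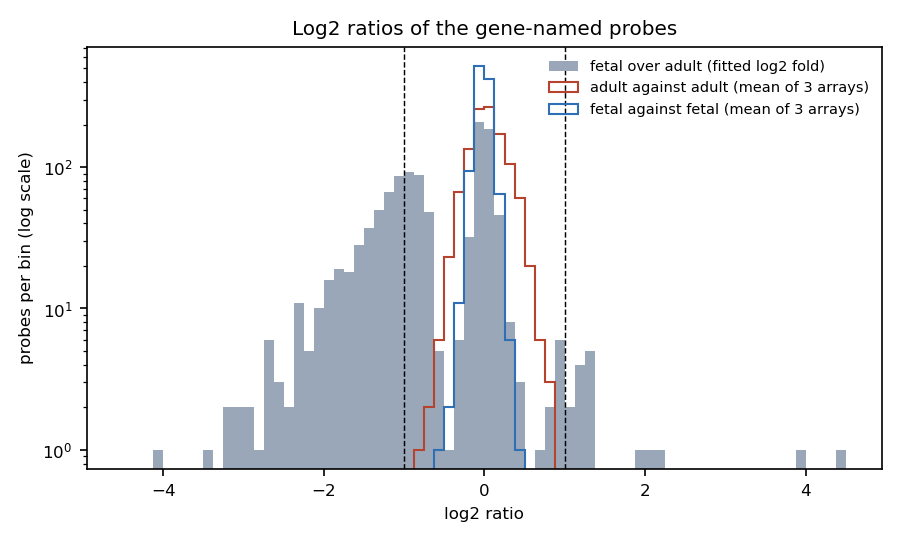
Number of probes (vertical axis, log scale) by log2 ratio (horizontal axis), for the fitted fetal over adult fold (filled) and for the mean of the 3 adult self and the 3 fetal self arrays (lines), with dashed lines at the fold minimum. The filled bars show a cluster at 0 and a second one below -0.5, with 7 probes between -0.5 and -0.25.

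Genes of energy metabolism lay on the adult side. Of 24 measured genes of oxidative phosphorylation and the citrate cycle, 16 were higher in adult RNA, 0 in fetal RNA and 8 did not pass the fold minimum, also when adjusted over the list alone (16 calls). With each array's median subtracted, 0 of the 24 passed the fold minimum. The list median was -1.06, against -0.68 for all other genes (cameraPR adjusted p = 0.00118, and adjusted p = 0.00138 with an estimated correlation). UQCR11 (-1.62, SE 0.0128) and UQCRQ (-1.54, SE 0.0247, 11 arrays), subunits of respiratory complex III, and SDHA (-1.40, SE 0.0302, 14 arrays), a subunit of succinate dehydrogenase, had the largest folds by the probe that stood for each gene. The other probe of UQCR11 was at -1.05 and that of SDHA at -1.09. Of 10 genes of fatty acid oxidation and uptake, 9 were higher in adult RNA (9 adjusted over the list alone), with a median of -1.36, and 1 with medians subtracted. ACADS (-1.91, SE 0.0491) and ACADM (-1.57, SE 0.0134, 17 arrays) are acyl-CoA dehydrogenases, and CPT2 (-1.56, SE 0.0272) is a carnitine palmitoyltransferase. The list stood apart from other genes at adjusted p = 0.00549, which became adjusted p = 0.0542 with an estimated correlation. Markers of fat cells, ADIPOQ and CIDEA, were higher in the same RNA, at -3.06 and -2.72. Of 3 measured genes of glycolysis, 2 were higher in adult RNA (2 adjusted over the list alone): PGAM2, the muscle form of phosphoglycerate mutase (-1.78, SE 0.0365), and PYGM, the muscle glycogen phosphorylase (-1.45, SE 0.0391). With medians subtracted, 1 of the 3 was called.

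Of 10 tested genes of the cardiac sarcomere and Z disc, out of 14 on the array, 5 were higher in adult RNA (5 adjusted over the list alone) and 5 did not pass the fold minimum, against 3 higher in adult RNA with medians subtracted. Their median was -1.27 (adjusted p = 0.0201, and adjusted p = 0.0214 with an estimated correlation). MYOM3, a myomesin of the M band, stood at -2.68 (SE 0.0205), and HSPB7, a small heat shock protein of heart, at -2.06 (SE 0.0249). CKMT2, the mitochondrial creatine kinase of muscle, stood at -1.78 (SE 0.0164). The list held it as fixed beforehand, so its counts include a gene that is not of the sarcomere or Z disc. Of 4 calcium and ion channel genes, 3 were higher in adult RNA (3 adjusted over the list alone): SLN, the small inhibitor of the calcium pump (-2.35, SE 0.0127, 11 arrays), HRC, a calcium-binding protein of the sarcoplasmic reticulum (-1.67, SE 0.0341, 17 arrays), and ATP2A2, the cardiac calcium pump (-1.42, SE 0.0232). With medians subtracted, 2 of the 4 were called. Both measured genes of the list of fetal contractile isoforms and natriuretic peptides were higher in adult RNA (2 adjusted over the list alone): TNNT1, the slow skeletal troponin T, at -1.18 (SE 0.0312, 15 arrays), and ACTA2, smooth muscle actin, at -1.06 (SE 0.0411, 14 arrays). With medians subtracted neither was called, at -0.50 and -0.39, and ACTA2 stood at -0.60 on the fetal red arrays alone. Skeletal muscle markers were higher in adult RNA too (3 of 3 measured, 3 adjusted over the list alone, and 2 with medians subtracted), with the myosin MYH2 at -2.32 (SE 0.0699), nebulin (NEB) at -2.04 (SE 0.0327), and PYGM.

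Of 6 measured genes of the cell cycle and DNA replication, 3 were higher in fetal RNA (KIF20A, ORC6 and CCNA2; 3 adjusted over the list alone), 0 in adult RNA and 3 did not pass, with the same counts after medians were subtracted. The list median was 0.79, against -0.73 for other genes (adjusted p = 0.0241, and adjusted p = 0.0519 with an estimated correlation). Of 2 growth and imprinted genes, IGF2BP1 was higher in fetal RNA (1 adjusted over the list alone). Of 8 extracellular matrix genes, COL5A2 was higher in fetal RNA, and TIMP4, an inhibitor of metalloproteinases found in heart, was higher in adult RNA (-1.33, SE 0.0189), with 2 calls adjusted over the list alone. The matrix list's median of -0.10 and mean of -0.11 lay below 0, and the median was 0.57 after each array's median was subtracted, when 2 genes were called higher in fetal RNA and 0 in adult RNA. Against other genes the list stood on the fetal side (adjusted p = 0.0419, and adjusted p = 0.0519 with an estimated correlation).

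Of 11 genes of antigen presentation, complement and inflammation, 9 were higher in adult RNA (9 adjusted over the list alone), and 1, IFI27, with medians subtracted. The list median was -1.15 (adjusted p = 0.0419, and adjusted p = 0.0635 with an estimated correlation). The interferon-induced genes IFI27 (-1.89, SE 0.00966) and IFIT1 (-1.64, SE 0.017) and the class II antigen loading protein HLA-DMA (-1.52, SE 0.0243) had the largest folds. The macrophage receptor MARCO was higher in the same RNA (-1.10, SE 0.0159, and -0.44 with medians subtracted). HLA-DRA, the class II chain that was the only one of the 17 textbook genes measured, stood at -1.001 (SE 0.0196, 17 arrays) and dropped below the fold minimum at -0.83 on the fetal red arrays alone. Of 7 developmental signalling genes, 3 were higher in adult RNA (3 adjusted over the list alone). These were FGF14-AS2 (-2.34, SE 0.0394), an antisense RNA, FGFBP2 (-1.56, SE 0.101), a secreted protein of cytotoxic lymphocytes, and the Notch ligand JAG2 (-1.05, SE 0.0206). JAG2 stood at -0.87 on the fetal red arrays alone. With medians subtracted, 1 gene of the list was called each way. The first 2 entered the list by the start of their symbols. The list did not stand apart (adjusted p = 0.305, and adjusted p = 0.396 with an estimated correlation), and its test pointed to the fetal side while its median (-0.95) and mean (-0.96) lay below those of other genes.

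Of 3 erythroid list genes, 2 were higher in adult RNA (2 adjusted over the list alone, and 1 with medians subtracted), the membrane skeleton proteins ANK1 (-2.20, SE 0.0116) and SPTB (-1.39, SE 0.0497), which muscle also makes. None of 3 cardiac transcription factors passed (0 adjusted over the list alone), with ZFPM1 at -0.77 (SE 0.0128) and TBX20 at 0.32 (SE 0.0368). The stress gene TSC22D3 stood at 0.09 (SE 0.0148), and of the ribosomal list RPL21 at 0.09 (SE 0.00597) and RPS27L at -0.69 (SE 0.0236), with 0 calls adjusted over the list alone in both.

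Of the 7 lists tested, 6 were called with the preset correlation and 2 with an estimated one. Each list was tested against the other genes on this array. A choice of probes by an earlier ratio between these tissues stays open, as described in the closing section. In that case members and other genes were both chosen by the quantity tested, and the list p-values would not hold for genes at large. Over the 18 mixed arrays alone 5 were called, and 5 of 100 random assignments of the orientations, the real one included, gave as many. That share reached the limit set before the test for a number that chance gives, so chance is not excluded. Such assignments can keep part of the contrast between the RNAs, so they do not show that chance alone gave this number.

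**Figure D3:**
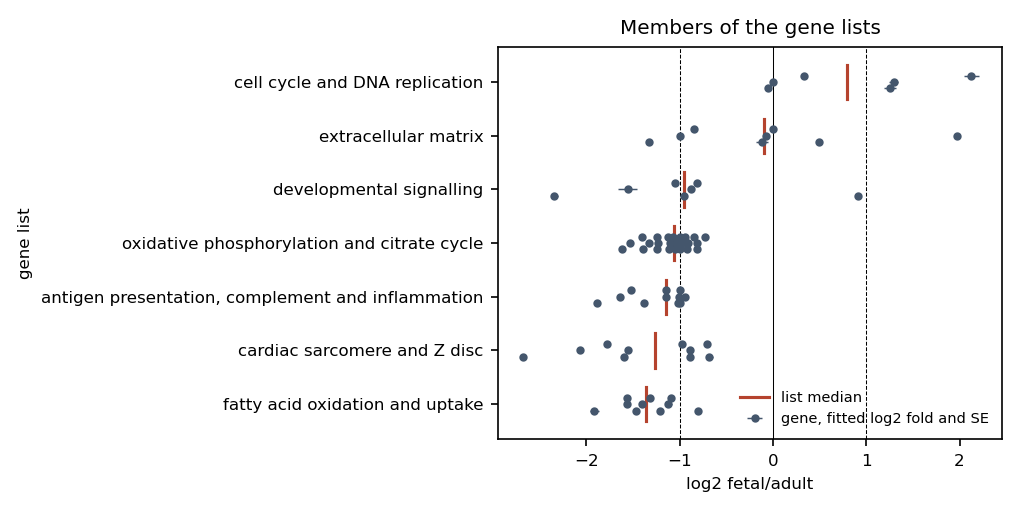
Fitted log2 fold of fetal over adult RNA (horizontal axis) with its SE for each gene of the 7 lists with at least 5 measured genes (vertical axis), with a bar at the list median. Cell cycle genes have a median of 0.79, and fatty acid oxidation genes of -1.36.

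Markers of other cell types and tissues were measured for 9 of 12 lists and 18 genes, of which 14 were higher in adult RNA and 0 in fetal RNA. Counts adjusted over each list alone were the same, and with medians subtracted 11 were higher in adult RNA and 0 in fetal RNA. Of all 1053 genes, 332 were higher in adult RNA and 16 in fetal RNA, so a lean to the adult side is not particular to these markers. With medians subtracted, 96 of 1119 probes were higher in adult RNA and 29 in fetal RNA. Both adipocyte markers were called, ADIPOQ and CIDEA (-2.72, SE 0.0443). Both epicardial and mesothelial markers were called, ITLN1 (-2.27, SE 0.0207) and CALB2 (-1.88, SE 0.076). So were both liver markers, transferrin (TF, -2.66, SE 0.0332, 15 arrays) and haptoglobin (HP, -1.74, SE 0.0178, 16 arrays), and the lung marker SFTPC. Of 4 markers of neurons and Schwann cells, CHGB and myelin basic protein (MBP, -1.11, SE 0.0127) were called. Of 2 smooth muscle markers, SYNPO2 was called (-1.98, SE 0.0164), although its other probe stood at -0.25. The fibroblast marker DCN, a matrix proteoglycan, stood at -0.84 (SE 0.016) and did not pass. Endothelial, lymphocyte, and neutrophil and mast cell markers had no measured gene here.

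The dye swap tested whether each array ran as its label says. After turning, each mixed array correlated with the mean of the others at a Pearson r of 0.961 to 0.986 across probes, which are not independent replicates. The mean ratios of the 2 orientations, before turning, correlated at -0.945 over the named probes. Over all spots, which include the unnamed ones far below 0 on the self arrays, the correlation was 0.60. The median over probes of the SD between arrays of a slide was 0.117 on the log2 scale, and 0.0423 once the dye bias was subtracted. Between slide means it was 0.0507, and 0.0296 without the dye bias.

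**Figure D4:**
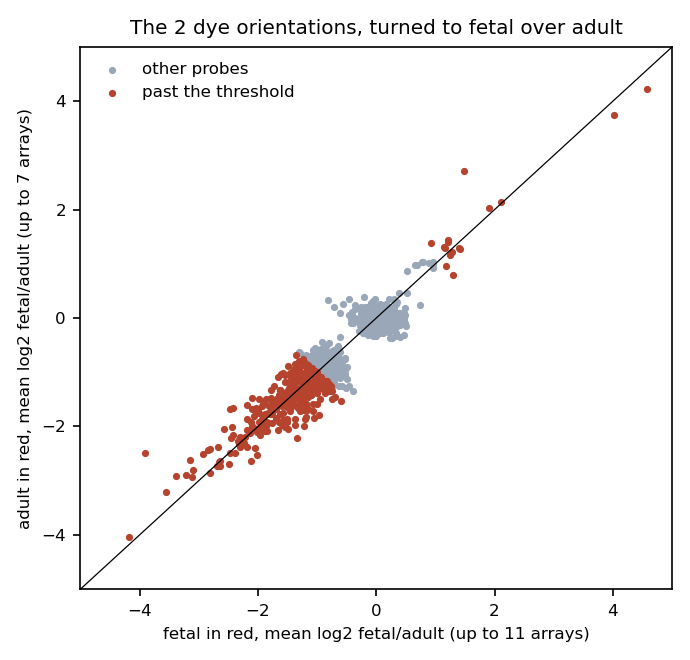
Mean log2 fetal over adult ratio per probe on the fetal red arrays (horizontal axis) and on the adult red arrays (vertical axis), with called probes in red and the line of equality. The probes follow the line, from -4.18 and -4.03 for DYNC1I1 to 4.58 and 4.22 for SPP1.

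Dye bias past the threshold was found in 3 probes, all towards green. These were FAM81B (-0.63), TMEM196 (-0.59) and IGF2BP1 (-0.58). TMEM196 stood at -0.82 on the fetal red arrays and 0.33 on the adult red arrays, and its fitted fold was -0.24 (SE 0.107, limma adjusted p = 0.041). FAM81B stood at -3.92 and -2.49, and IGF2BP1 at 1.49 and 2.71, so that both kept their direction in each orientation. Without the fold minimum, limma found a dye bias in 782 of 1119 probes.

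The self arrays gave the level that ratios reach with no difference in RNA. No probe had a mean log2 ratio beyond 1 in size on them (0 on adult and 0 on fetal self arrays), and 20 and 0 went beyond 1.5-fold. The SD over probes was 0.2499 ± 0.00299 (SD, n = 3) on adult self arrays and 0.122 ± 0.0159 (SD, n = 3) on fetal self arrays, against 0.817 ± 0.0352 (SD, n = 11) on fetal red and 0.798 ± 0.0264 (SD, n = 7) on adult red arrays. Dye bias differed between adult and fetal self arrays for 595 of 1071 probes in limma, 223 with a higher red over green ratio in fetal RNA and 372 in adult RNA. Of these, 48 differed by at least 0.5. SPTB differed most, at 0.76 on adult and -0.04 on fetal self arrays. IGF2BP1 stood at -0.83 and -0.14.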

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

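Tests of the channel offset, the normalization, the choice of probes and the fat genes within muscle cells were chosen after the result was seen, as were the values for unnamed spots. Of 65 tests for an array far from the rest of the 7 adult red arrays, 9 were past the limit. Chance passes that limit about 1 in 20 times for continuous values. Most deposited ratios stood in steps, and arrays often shared a value, as all others did for ACADM at -1.46. With such ties the rate of 1 in 20 does not hold, so the 9 are not shown to exceed chance. In each of the 9 tests, 1 array stood apart, with a log2 fetal over adult ratio of 2.13 for COL5A2, -2.66 for MYOM3, -1.53 for ACADM, -1.69 for UQCR11, -1.16 for JAG2, -1.73 for HLA-DMA, -0.0664 for TSC22D3 and -2.39 for ITLN1. For TMEM196, a probe with a large dye bias, it was 1.10. The first 8 lay at most 0.144 from the mean of the other arrays.

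A test of slide by polarity in limma found 91 of 1104 probes whose fetal over adult ratio differed between slides, 13 of them by at least 0.5. EXO1 differed most, at 1.60, 0.59 and 1.07 on the 3 slides, and FGFBP2 stood at -2.11, -1.18 and -1.53. Of 100 random assignments of the slides, 1, the real one, gave as many, and the highest other gave 40. This share lay under the limit set before the test for a count that chance gives. It is also the smallest share that 100 assignments can give, so chance is unlikely for this count but not excluded. EXO1 and FGFBP2 were largest in size on slide 1 and smallest on slide 2. The SD over probes of the mixed arrays ran in the same order, at 0.838 to 0.851 on slide 1, 0.781 to 0.832 on slide 3 and 0.758 to 0.788 on slide 2. Slide-wide differences in the size of ratios were therefore not told apart from differences of single probes. Among spots with no gene name and a self ratio within 1, 129 of 537 passed the threshold of the main comparison, 6 higher in fetal RNA and 123 in adult RNA. A further 155 unnamed spots had a mean log2 ratio below -1 on the self arrays, with a median of -5.37.

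The first pattern is the excess of probes higher in adult RNA (368 against 16), which would be an excess in fetal RNA if the ratio ran the other way. Over the 18 mixed arrays, the counts of the directions differed by 350. Of 100 random assignments of the orientations, 1, the real one, gave as much (highest other 173). The total of 382 calls was likewise reached by 1 of 100 (highest other 183). All mixed arrays held the same pair of RNAs as far as the labels say, so a wrong assignment largely cancels the ratios. The result shows that the ratios turned with the dyes, and cannot test why more probes lay on the adult side. An offset between the red and green channels is argued against by the dye swap, since each orientation alone gave the excess (377 against 15 on fetal red and 385 against 19 on adult red arrays), and the median log2 red over green ratio, -0.67 and 0.65 in the mean over arrays, had -0.014 shared by both. A normalization that set the wrong probes to 0 in both orientations stays open, since the main peak within 0.025 of 0 on every mixed array is also where a normalization that centres it would put it. A choice of probes by an earlier ratio between these tissues stays open as well, since the band from -0.5 to -0.25 held 3.87% as many probes as the smaller of its neighbouring bands, but this gap was what prompted the explanation, and a difference between fetal and adult hearts is untested, with 1 RNA of each stage.

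The second pattern is that genes of fat tissue were far higher in adult RNA. A candidate explanation is fat cells in the adult RNA. Of 9 further genes that fat tissue uses, listed before their own values were looked at but after the probes with the largest folds had been seen, 7 were called on the adult side (77.8%, median -1.73), among them DGAT2 (-1.99), SCD (-1.48) and PNPLA2 (-1.73), against 30.9% of 1040 other genes (one-sided Fisher's exact p = 0.00538). Heart muscle also uses several of these, PNPLA2 and MGLL (-0.73) among them, and the abundant fat cell genes PLIN1 and LEP were not measured here. A change within heart muscle cells stays open, since ADIPOQ at -3.06 comes from RNA of whole tissue.

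The third pattern is the dye bias that differed between adult and fetal self arrays. A split of 6 arrays has 10 forms, too few for a share under 0.05, and the real one gave 595 probes, as many as 1 of the 10, while the highest other gave 0. A labelling that differed between self and mixed arrays would keep the sum of both orientations from matching the sum of both self means, and 0.468% of probes departed, which argues against it, and labelling reactions that differed between slides are argued against too, since the difference correlated across probes at 0.631 or more between slides. Whether the bias may follow how much of a transcript the RNA holds cannot be told apart from other sources, since its Spearman correlation with the fold was 0.17 across 1068 probes, between the limits set before. Arrays that shared 1 labelling of each RNA per dye would also give these values, and no biological explanation was tested.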

How the results depend on the processing

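Unnamed spots, zeros as missing and the narrower signalling list were chosen after seeing the data, and the cause of the changes below was not tested except where the setting itself shows it. With each array's median subtracted, 125 probes were called (29 fetal, 96 adult), of which 112 were shared with the 384, and scaling the mixed arrays as well gave the same counts of 125, 29 and 96. A 1.5-fold minimum gave 627 (25 and 602), the same minimum inside the test 624 (25 and 599), and no minimum 900 (160 and 740). Read as log2 already, the values gave 4 (2 and 2). All other settings, unnamed spots and zeros included, kept the 3 counts within 1.5 times of 384, 16 and 368. Leaving out 1 mixed array gave 372 to 384 (16 to 16 and 356 to 368), and leaving out 1 slide 342 to 380 (14 to 19 and 323 to 364). The dye bias count of 3 became 0 on the 6 self arrays, 8 on the 18 mixed arrays, 782 without a minimum and 3 to 5 without 1 slide, with 5 when slide 3 was left out. Dye bias that differed between self arrays ranged from 483 to 540 probes without 1 array. On adult self arrays 20 probes went beyond 1.5-fold, and 0 to 1 beyond 2-fold without 1 array, with 1 when the first replicate was left out. Subtracting the dye bias lowered the SD to 0.0423 within and 0.0296 between slides. With the slide as a block, which pairs the self arrays, 516 probes differed between them in place of 595, and 379 in place of 384 differed between fetal and adult RNA. Beyond the slide, no paired analysis was possible because the labels number slides and positions only, not replicates.

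With an estimated correlation, adjusted p was 0.0542 for fatty acid oxidation, 0.0519 for the cell cycle, 0.0519 for matrix and 0.0635 for antigen presentation, so 2 of 6 lists stayed called. Over all settings these 4 ranged from 8.06e-06 to 0.0542, 7.65e-05 to 0.0601, 0.0335 to 0.237 and 0.00387 to 0.0635. The cell cycle list had adjusted p = 0.0601 on fetal red arrays. Matrix had 0.0957 by log2 fold, 0.0625 with medians subtracted, 0.155 on fetal red and 0.237 on adult red arrays. Developmental signalling turned to the adult side by log2 fold (adjusted p = 0.253, with 0.198 to 0.814 over all settings). Without 1 slide, antigen presentation ranged from 0.0343 to 0.0557, and it lost its call without slide 1. On the 18 mixed arrays 5 lists were called, and 5 of 100 random assignments of the orientations, the real one included, gave as many (highest other 5). A list is tested against other genes, and such an assignment can keep a weak part of the contrast between the RNAs. An assignment with 5 lists called had 0 probes called. The share of 5 of 100 reached the limit set before the test for a number that chance gives, so chance is not excluded. Since part of the contrast can be kept, the test does not show that chance alone gave this number of lists. Of the 63 named probes, 56 were called, and 18 of these fell under the fold minimum with medians subtracted, 3 on fetal red arrays, 1 with the slide as a block, 1 without slide 1 and 1 without slide 2. TMEM196 turned to 0.42 with medians subtracted and to 0.33 on adult red arrays. Signal over background was not used here, so what weak spots limit is unknown.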

Other observations

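Beyond the 10 probes named by size, 6 more were higher in fetal RNA, and they are named here after their values were seen. CXCR4, the receptor of a chemokine that guides migrating cells, stood at a log2 fold of 1.23 (SE 0.0283, 17 arrays). PMAIP1, a promoter of cell death, stood at 1.22 (SE 0.0546), and PTPRH, a receptor tyrosine phosphatase, at 1.20 (SE 0.0268). The mismatch repair protein MSH6 was at 1.15 (SE 0.0256, 16 arrays) and the exonuclease EXO1, which acts in the same repair pathway, at 1.08 (SE 0.123). PNMT, the enzyme that makes adrenaline from noradrenaline, was at 1.04 (SE 0.0324). Each was higher in fetal RNA on every mixed array with a value.

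ACTB and GAPDH, often used as reference genes, are also named after their values were seen. The 3 probes of ACTB ranged from -0.86 to 0.34, and GAPDH stood at -0.80, so probes of a single reference gene differed in direction here. GAPDH and all 3 probes of ACTB were among the probes whose dye bias differed between the self arrays, with GAPDH at 0.61 and the ACTB probes at 0.23 to 0.78 on adult self arrays, and at -0.04 and 0.03 to 0.12 on fetal self arrays.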
